A study of Mus musculus with 4 samples.

How the data were processed

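The 4 libraries were 10x Genomics droplet single-cell RNA libraries of sorted mouse thymocytes, 2 from control and 2 from LRF-deficient mice. Per the labels, the replicate 1 pair was made with the Single Cell 3′ v2 kit and the replicate 2 pair with the V(D)J 5′ kit, v1.1 chemistry. The deposited matrices hold whole-number UMI counts per gene and barcode, not normalized. Per the file headers the counts of the replicate 1 pair came from Cell Ranger 3.0.0, and per the submitters' processing notes bcl2fastq 2.17 was used for that pair and Cell Ranger 5.0.0 for the replicate 2 pair, on mm10. The deposited counts of the replicate 1 pair cover called cells only (4887 and 5841 barcodes), and those of the replicate 2 pair cover 737280 barcodes each, most of them empty. The annotations list 31053 and 32285 genes, and the 30406 genes present in both were used, which held 99.5% to 99.8% of UMIs. Gene coordinates are those of GENCODE vM21 on mm10 (GRCm38).

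Groups came from the genotype labels and titles. The titles number only the second pair, as replicate 2, and the other pair was numbered 1 here. The labels' protocols give a library kit for each pair, so the libraries of 1 kit were treated as pairs. The deviations of same-numbered libraries from their group means had a correlation of 0.94 over genes. The designs, the gene lists, the cell type markers, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Choices made later are named as chosen after the data were seen.

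Cells were called in the replicate 2 libraries as barcodes above 1/10 of the 99th percentile of the top 3000 barcodes, which gave thresholds of 2453 and 2089 UMIs. Kept cells had at least 500 genes and at most 10% mitochondrial UMIs. In the replicate 1 pair the mitochondrial bound removed 607 of 4887 control and 266 of 5841 LRF-deficient barcodes. The gene bound was missed by 374 and 224 of them, so quality differed between the groups in that pair. Doublets were scored from simulated pairs of cells within each library with 40 nearest neighbours on 20 principal components. The top-scoring 0.8% per 1000 cells were left out, which was 139 and 245 cells of the replicate 1 control and LRF-deficient libraries and 315 and 358 of the replicate 2 libraries. The number removed was set by this expected rate and not estimated from the scores. The median depth of passing cells was 3982 and 3208 UMIs with the 3′ kit and 5608 and 4933 UMIs with the 5′ kit, control first. Barcodes of at most 300 UMIs held 17.9% and 14.3% of the UMIs of the replicate 2 libraries.

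Counts of kept cells were summed per library, since cells are not replicates. Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by its quasi-likelihood test after filterByExpr and TMM, with kit and genotype as terms, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. With 4 libraries this leaves 1 residual degree of freedom, and the spread is moderated over genes (prior degrees of freedom 5.18). CPM are counts per 1000000 of a library's TMM-scaled total. Fold changes are those of the libraries labelled LRF-deficient over control. The 28 gene lists were gut homing and adhesion, thymic egress and recirculation, agonist TCR signal, T-bet program, CD8 lineage, CD4 lineage, regulatory T cell, PLZF innate-like T cell, gamma-delta T cell, cortical double-positive thymocyte, Notch targets, glycolysis, apoptosis, interferon response, NF-kB response, TGF-beta response, dissociation and immediate early, cell cycle, globin, zinc finger and lineage regulators, T cell receptor complex and signalling, MHC class I, sex-linked check, B cell, myeloid and dendritic cell, NK cell, erythroid, and thymic epithelium and stroma. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

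The rule for named genes took Zbtb7a, then the 12 largest rises and 12 largest falls among genes past the threshold, with the same direction in both kits and a mean of at least 10 CPM. It left out receptor segments, mitochondrial and ribosomal genes, sex-linked genes and unnamed gene models. Itgb7, Itga4, Itgae, Ccr9 and Pdcd1 were named in all cases, at most 4 members per list by smallest p, and 3 rises and 3 falls per cluster. List members beyond these were named after their values were seen, which were S1pr1 and Nr4a1. Some members of the lists and markers are not reported here, though counted in their lists.

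Clusters were made from 2000 variable genes, scaled within each kit, 30 principal components, 20 nearest neighbours and Leiden partitioning (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 0.8. Resolutions of 0.4 and 1.2 gave 7 and 18 clusters, and scaling within each library gave 14. A cluster was named when at least 3 markers of a type were among its 30 leading genes. No cluster was named for a type other than T cells, so none was left out. A further clustering replaced the 220 variable genes that passed the threshold between the groups by the next most variable ones. It was chosen after the data were seen, and so were the fits without the low-quality cluster 11 and without the cycling clusters. Another clustering that dropped genes at an unadjusted p under 0.05 was made and not analysed. Cell numbers per cluster were tested with edgeR with kit and genotype as terms and total cells as library size. A test of the same numbers summed per named type was also run. Differences of the genotype effect between clusters were tested with library as a block.

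Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, leaving out shallower cells (61 and 16 with the 3′ kit), with exact binomial intervals at 95%. UMIs remove amplification copies, and intervals cover counting error only. Segment shares were taken from the 5′ pair, and the sum of their differences was set beside that with cells dealt at random, a comparison chosen after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used. DESeq2 1.42.0 was an alternative.

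The tests were first tested on simulated data with the means and library sizes of the real genes. The genes changed in the simulations all had a mean of at least 10 CPM, so recovery below that level is not known. Of 50 genes changed at each size in the comparison over all kept cells, edgeR with the kit term recovered 5 at 1.2-fold, 44 at 1.5-fold, 50 at 2-fold and 50 at 4-fold, and called 18 of the unchanged of 12473 genes. These 18 beside 149 recovered genes are a larger share than the nominal 5%. Without the kit term, or with 1 library left out, it recovered 0 of 200, so those fits cannot show stability. DESeq2 recovered 126 of 200 and called 7 unchanged genes. The test of differences between clusters was simulated with fewer clusters than the real data. The simulated change was in a single cluster and larger than the ranges flagged below for Cd7, Cks1b, Hmgn2 and Ms4a4b. It recovered 99 of 100 such genes and called 19 unchanged genes, which does not give its recovery in the real data. Camera found the raised list with the preset correlation (p = 1.42e-116), but with an estimated correlation that list had p = 0.0541 and was missed. The simulated genes varied independently of each other, so this does not check the camera p-values of lists whose genes vary together. The reason for the miss was not tested. Since a list with every member raised was missed, a miss with an estimated correlation cannot check a list. It does not show that a list is unchanged.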

Results

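Precursors of intraepithelial lymphocytes (IELp), thymocytes that give rise to unconventional T cells of the gut epithelium, were profiled by droplet single-cell RNA sequencing in C57BL/6 mice. The sorted cells were TCRβ-positive, lacked surface CD4, CD8α and CD44, and were CD5-high, CD122-positive, H-2Kb-positive and PD-1-high. Control mice carried floxed alleles of the gene for LRF, a zinc finger transcription factor encoded by Zbtb7a, without Cre. LRF-deficient mice carried the same alleles with Cd4-Cre, so the presence of Cre went with the genotype. Each group had 2 libraries, 1 made with the 10x 3′ v2 kit (replicate 1) and 1 with the 10x 5′ V(D)J v1.1 kit (replicate 2). After filtering, the 3′ kit gave 4029 control cells and 5289 cells labelled LRF-deficient, with 18204344 and 18996185 UMIs. The 5′ kit gave 5963 and 6330 cells, with 39860060 and 36228305 UMIs. The labels do not say whether the pairs came from separate mice, so p-values measure the spread between these libraries.

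The comparison of genotypes asked which transcripts of IELp differ when LRF is deleted. Zbtb7a itself (ENSMUSG00000035011, chromosome 10, 81135220 to 81152995, mm10) was higher in the libraries labelled LRF-deficient. Its level was 113 counts per 1000000 (CPM, scaled by TMM) in the control and 332 in the library labelled LRF-deficient with the 3′ kit, and 98.1 and 206 with the 5′ kit. The fitted log2 fold change of Zbtb7a was 1.31 (SE 0.116, n = 2 per group, edgeR adjusted p = 0.00378). This goes against the labels. The floxed exons are not named in the labels, so the counted part of the transcript may lie outside the deletion, in which case the level does not check the labels. Every direction below therefore follows the labels as given. Without the kit term the fold change was 1.35 (adjusted p = 1), and with 1 library left out it lay between 0.94 and 1.65 and missed the threshold.

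**Figure D1:**
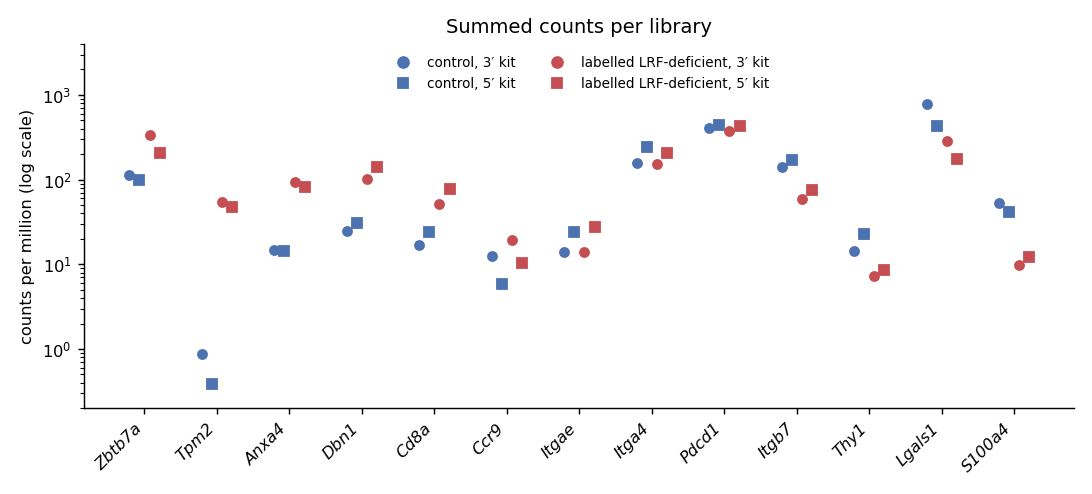
CPM on a log axis for 13 genes in each of the 4 libraries, with 1 point per library, circles for the 3′ kit and squares for the 5′ kit. Zbtb7a, Tpm2, Anxa4, Dbn1, Cd8a and Ccr9 lie higher, and Itgb7, Thy1, Lgals1 and S100a4 lower, in the libraries labelled LRF-deficient within each kit; Itga4, Itgae and Pdcd1 did not pass the test.

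Over all kept cells, 683 of 12473 tested genes passed an adjusted p of 0.05, of which 350 were higher and 333 lower in the libraries labelled LRF-deficient. Among genes with a mean of at least 10 CPM, outside receptor segments and unnamed gene models, the largest rise was that of Tpm2 (tropomyosin 2, chromosome 4, 43514711 to 43523765), from 0.875 to 54.0 CPM with the 3′ kit and from 0.385 to 48.1 with the 5′ kit. Its log2 fold change was 6.54 (SE 0.186, n = 2 per group, adjusted p = 0.000179). The 11 other largest rises at this level were those of Pdzk1, a PDZ scaffold protein (log2 fold change 3.17), Pnmt, the enzyme that makes adrenaline (3.13), Gng3, a G protein gamma subunit (3.04), Crhbp, which binds corticotropin-releasing hormone (2.94), and Rcn3 (2.79), followed by Anxa4, an annexin (2.57), Arhgef25 (2.30), Apoe, the lipid carrier (2.19), Dbn1, an actin-binding protein (2.13), Sh3rf1 (1.89) and Clstn1 (1.85). Their standard errors ran from 0.0783 for Dbn1 to 0.147 for Pnmt. Adjusted p-values ran from 0.000179 for Pdzk1 to 0.00194 for Clstn1.

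The 12 largest falls at this level were led by S100a4, a calcium-binding protein of activated and memory T cells (log2 fold change −2.06, SE 0.151, adjusted p = 0.00195), which went from 53.2 to 9.83 CPM with the 3′ kit and from 41.9 to 12.1 with the 5′ kit. The others were Hist1h2ap (−1.92), Ms4a6b (−1.74), Hcst, the DAP10 adaptor (−1.61), Tmem158 (−1.57), H2-Q6 (−1.50) and Myl1 (−1.43), then Lgals1, which encodes galectin-1 (−1.37), Irgm1, an interferon-inducible GTPase (−1.26), Thy1 (−1.23), Itgb7 (−1.21) and Akip1 (−1.20). The least certain of them were Irgm1 (SE 0.2503, adjusted p = 0.0437) and Hist1h2ap (SE 0.332, adjusted p = 0.0292). Hist1h2ap and H2-Q6 belong to families of near-identical genes, so their counts are uncertain. Irgm1 and Hist1h2ap missed the threshold under a stricter expression filter (edgeR adjusted p = 0.0798 and 0.0562). In edgeR without the kit term no gene passed (0, with 384 at an unadjusted p under 0.05). Leaving out any 1 library, which also removes the kit term, left 0 genes (125 to 191 at an unadjusted p under 0.05), and DESeq2 with the kit term called 338. Fits with 1 library left out compare libraries of different kits. Their fold changes, wherever given in this text, therefore also carry the kit difference. In them the log2 fold changes of 4 of these falls moved by over 1.5 times. Hist1h2ap went to −1.003 without the LRF-deficient replicate 1, −1.05 without the control replicate 2 and −4.34 without the LRF-deficient replicate 2, and Myl1 to −0.864, −2.19 and −0.814 without the control replicate 1 and the LRF-deficient replicates 1 and 2. Lgals1 went to −0.891 without the control replicate 1, and Irgm1 to −0.757 without the LRF-deficient replicate 2.

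The genes of gut homing were reported in all cases. Itgb7 (chromosome 15, 102215995 to 102231944) encodes integrin β7, which pairs with the α4 chain to bind MAdCAM-1 in gut vessels and with the αE chain to bind E-cadherin. Itgb7 fell by 1.21 on the log2 scale (SE 0.067, n = 2 per group, adjusted p = 0.000921), from 140 to 59.0 CPM with the 3′ kit and from 172 to 76.0 with the 5′ kit. Its partner chains did not pass the test, with a log2 fold change of −0.11 for Itga4 (adjusted p = 0.422) and 0.12 for Itgae (adjusted p = 0.544). Ccr9, the receptor for the intestinal chemokine CCL25, rose by 0.72 (SE 0.112, adjusted p = 0.0204). Pdcd1, which encodes PD-1 and on which the cells were sorted, had a log2 fold change of −0.08 (adjusted p = 0.525). Of the 14 tested genes of gut homing and adhesion 1 rose and 1 fell over all genes, 2 rose and 4 fell adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.106). DESeq2 did not call Ccr9 (adjusted p = 0.0965), whose log2 fold change was 1.34, 0.144 and 0.236 without the control replicate 1, the LRF-deficient replicate 1 and the control replicate 2. In barcodes of at most 300 UMIs from the 5′ kit Ccr9 was at 12.2 CPM (here not scaled by TMM) in the control against 6.52 in its cells, and at 13.85 against 11.1 in the library labelled LRF-deficient, so its level in the cells did not exceed that of free RNA.

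Counts of CD8 coreceptor transcripts were higher in the libraries labelled LRF-deficient, although the cells had been sorted as lacking surface CD8α. Cd8a (chromosome 6, 71373427 to 71379173) rose by 1.65 on the log2 scale (SE 0.0756, n = 2 per group, adjusted p = 0.000465), from 17.0 to 51.5 CPM with the 3′ kit and from 24.2 to 77.5 with the 5′ kit. In the 5′ control its level in cells did not exceed that of free RNA (26.8 against 29.3 CPM, not scaled by TMM). In the 5′ library labelled LRF-deficient it was at 83.4 in cells against 66.6. Cd8b1 rose by 0.83 (adjusted p = 0.0174), although in barcodes of at most 300 UMIs from the 5′ kit it was at 19.5 CPM (here not scaled by TMM) in the control against 7.70 in its cells, and at 18.7 against 13.4 in the library labelled LRF-deficient, so its level in the cells did not exceed that of free RNA. Cst7, which encodes cystatin F, fell by 0.74 (adjusted p = 0.00757). The CD8 lineage list held 2 members that rose and 1 that fell of 12, both over all genes and adjusted over the list alone, and did not pass as a list (adjusted p = 0.341; its median was below 0 while the test pointed up). Of 9 CD4 lineage genes 2 fell over all genes and 5 adjusted over the list alone (camera adjusted p = 0.00253; adjusted p = 0.552 with an estimated correlation), Cd4 by 2.11 (adjusted p = 0.0369) from 0.875 and 1.83 CPM in the controls, and Socs1, a cytokine signalling inhibitor, by 0.39. With 1 library left out the log2 fold change of Cd8b1 lay between 0.51 and 1.15, of Cd4 between −2.46 and −1.40 and of Socs1 between −0.649 and −0.168.

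Of the 28 gene lists 12 passed camera, each with a lower level in the libraries labelled LRF-deficient. The list with the smallest p was the interferon response, in which 13 of 35 members fell and 0 rose over all genes, and 28 fell adjusted over the list alone (camera adjusted p = 6.94e-18; adjusted p = 0.552 with an estimated correlation). Among its members, Ifi27l2a fell by 0.95 (SE 0.0647), Ly6a by 2.96 (SE 0.307), Ifi209 by 0.61 (SE 0.0727) and Xaf1 by 0.55 (SE 0.0816). MHC class I genes followed, with 8 of 15 lower over all genes and 14 adjusted over the list alone (adjusted p = 4.35e-13; adjusted p = 0.552 with an estimated correlation). H2-K1 fell by 0.44 and H2-D1 by 0.48 on the log2 scale, and H2-Q7, whose reads are hard to tell from those of H2-Q6, by 1.19. The cells had been sorted as H-2Kb-positive, the product of H2-K1. With 1 library left out the log2 fold change of H2-K1 lay between −0.705 and −0.218, of Ifi27l2a between −1.24 and −0.622 and of Ly6a between −3.51 and −1.897.

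Of 40 cell cycle genes 8 fell over all genes and 24 adjusted over the list alone (camera adjusted p = 1.9e-09; adjusted p = 0.552 with an estimated correlation), among them Tyms (log2 fold change −0.85), Rrm2 (−0.67) and Ccna2 (−0.61). Of 12 genes of thymic egress and recirculation 3 fell over all genes and 5 adjusted over the list alone (adjusted p = 0.000369; adjusted p = 0.552 with an estimated correlation). Among them were Il7r (−0.80) and Klf3 (−0.33), while S1pr1, the receptor that guides exit from the thymus, had a log2 fold change of −0.12 (adjusted p = 0.347). Of 13 genes of PLZF innate-like T cells 4 fell and 1 rose over all genes, with 7 lower and 1 higher adjusted over the list alone (adjusted p = 9.38e-05; adjusted p = 0.552 with an estimated correlation). Zbtb16, which encodes PLZF, fell by 1.15, Icos by 1.08 and Klrb1c by 1.54, and Plac8 rose by 0.89. With 1 library left out, which drops the kit term, Ccna2 lay between −1.46 and 0.116, the rise being without the control replicate 2. In the same fits Rrm2 lay between −1.12 and −0.313, Klf3 between −0.462 and −0.2101, Zbtb16 between −1.89 and −0.677 and Plac8 between 0.248 and 1.61.

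Of 6 other lists with a lower camera result, none passed with an estimated correlation (adjusted p = 0.552 for each). NF-kB response genes had 3 lower and 1 higher of 17 (adjusted p = 0.000266), with Cd83 down (log2 fold change −3.65, from 5.89 and 4.75 CPM in the controls) and Icam1 up (0.47). Regulatory T cell genes had 2 lower of 12 (adjusted p = 0.00212), Foxp3 (−1.95) and Capg (−0.70), and gamma-delta T cell genes 1 lower of 11 (adjusted p = 0.00454), Cd163l1 (−3.63, at most 0.724 CPM). The agonist TCR signal list had 4 lower of 26 (adjusted p = 0.023), Bcl2a1b, Icos, Bcl2a1d and Tagap, of which Bcl2a1b fell by 2.02, and Nr4a1, the usual reporter of TCR signal strength, was at 0.12 (adjusted p = 0.495). Apoptosis genes had 3 lower of 18 (adjusted p = 0.023), Bcl2a1b and Bcl2a1d, survival genes of the BCL2 family with near-identical copies, and Fas. The T-bet program had 4 lower and 2 higher of 24 (adjusted p = 0.0305), with Ly6c2 (−1.01) and Xcl1 (−0.87) lower and Zeb2 (0.75) and Ccl5 (0.73) higher. Adjusted over the list alone, 7 NF-kB, 3 regulatory T, 1 gamma-delta, 4 agonist, 4 apoptosis and 8 T-bet genes were lower, and 1 NF-kB and 3 T-bet genes higher. With 1 library left out Ccl5 lay between 0.167 and 1.34, Zeb2 between 0.494 and 1.01, Xcl1 between −1.16 and −0.575, Tagap between −0.695 and −0.227 and Fas between −0.769 and −0.312. Of the lists with tested members fry gave none a p under the threshold (smallest adjusted p = 0.12 for a one-way change and 0.0632 for a change either way).

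The other lists did not pass camera. Cortical double-positive thymocyte genes had 2 higher and 1 lower of 14 (adjusted p = 0.106), Notch targets 2 higher and 1 lower of 9 (0.385), glycolysis 1 higher of 19 (0.492), the TGF-beta response 1 higher of 14 (0.471), zinc finger and lineage regulators 1 higher of 23 (0.471) and the T cell receptor complex 1 lower of 20 (0.942). Dissociation and immediate early genes had 0 of 16 changed (0.375), and the sex-linked check 0 of 4 (0.341). Adjusted over the list alone, the changed genes were 3 higher and 1 lower for the double-positive list, 2 and 2 for Notch targets, 3 and 0 for glycolysis, 2 and 0 for TGF-beta, 2 and 0 for the regulators, 0 and 1 for the receptor complex, and 0 for both of the last lists. Notch targets and glycolysis had medians just below 0 with a test that pointed up.

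Markers of other cell types did not pass as lists. B cell genes had 1 higher and 1 lower of 7 (adjusted p = 0.540), with Cd74 down (log2 fold change −2.70) and Ighd up (0.70). Myeloid and dendritic cell genes had 1 higher and 1 lower of 6 (0.823), and NK cell genes 1 and 1 of 7 (0.341), with Tyrobp, an adaptor shared by both lists, higher (0.83). Epithelial and stromal genes had 1 lower of 3 (0.341), Pecam1 (−0.60). With 1 library left out Ighd lay between 0.337 and 1.05 and Pecam1 between −0.909 and −0.29. Adjusted over the list alone, 2 B cell genes were higher and 2 lower, 1 and 2 for myeloid, 1 and 4 for NK, and 0 and 2 for stroma. The myeloid list had a median above 0 with a test that pointed down. No member of the erythroid and globin lists had enough counts to test.

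Fold changes were compared between the kits, whose pairs share no library. Across 7627 genes with at least 10 CPM, the log2 fold changes of the 3′ and 5′ pairs had Pearson's r = 0.653 (95% bootstrap interval 0.604 to 0.703) and a Spearman correlation of 0.473, a description across genes, which are not independent replicates. The sign was shared by 66.9% of these genes. Tpm2 had log2 fold changes of 5.84 and 6.73, Gng3 of 3.03 and 3.03, Anxa4 of 2.64 and 2.49, Itgb7 of −1.24 and −1.18, and S100a4 of −2.43 and −1.79. Hist1h2ap and Irgm1 differed most among the named falls, at −3.48 and −1.48 and at −0.63 and −1.79.

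**Figure D2:**
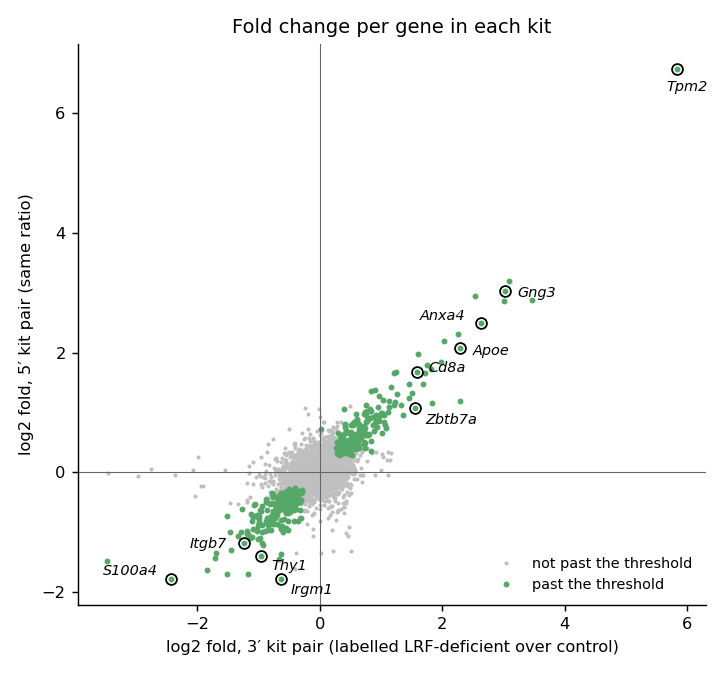
Log2 fold change of each gene with at least 10 CPM, library labelled LRF-deficient over control, with the 3′ kit pair on the x axis and the 5′ kit pair on the y axis. Green points passed the adjusted p of 0.05 and circled genes are named; the cloud of 7627 genes has r = 0.653, and Tpm2 lies apart at 5.84 and 6.73.

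The share of cells in which Itgb7 was detected was compared at a fixed depth of 1000 UMIs per cell. With the 3′ kit Itgb7 was found in 11.97% of 3968 control cells (exact 95% binomial interval 10.98 to 13.02) and in 4.53% of 5273 cells labelled LRF-deficient (3.99 to 5.13). With the 5′ kit the shares were 16.2% of 5963 cells (15.2 to 17.1) and 7.60% of 6330 cells (6.96 to 8.28). The difference was −7.44 and −8.55 percentage points in the 2 kits, a mean of −7.995 ± 0.787 (SD, n = 2 pairs). Intervals cover counting error only, and an exact permutation test of 2 libraries against 2 cannot reach a p under 0.05, so none was run. Without thinning the shares were 36.8% and 14.99% with the 3′ kit and 54.1% and 29.4% with the 5′ kit, at median depths of 3950, 3188, 5481 and 4771 UMIs.

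Cd8a showed the opposite, with a UMI in 1.03% and 4.27% of cells with the 3′ kit and 2.01% and 6.92% with the 5′ kit, control first. Tpm2 was found in 0.0504% and 4.23%, and in 0.0335% and 4.66%, and Zbtb7a in 10.6% and 26.5%, and in 10.5% and 20.5%. No cluster was named for a cell type that should lack these genes, so no background share is given for them, and their levels in barcodes with few UMIs are set beside those in cells. In barcodes of at most 300 UMIs from the 5′ kit, Itgb7 had 79.9 CPM (here not scaled by TMM) in the control against 191 in its cells, and 39.2 against 81.7 in the library labelled LRF-deficient. Cd8a in such barcodes was at 29.3 CPM against 26.8 in cells of the control and 66.6 against 83.4 in the other library, and Tpm2 was at 0.896 against 0.427 and at 48.5 against 51.8. Zbtb7a was at 56.0 against 108.8 and at 108.7 against 221.8. Free RNA thus carried these genes and differed between the groups in the direction of the cells, and its part in each cell's counts was not estimated here.

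**Figure D3:**
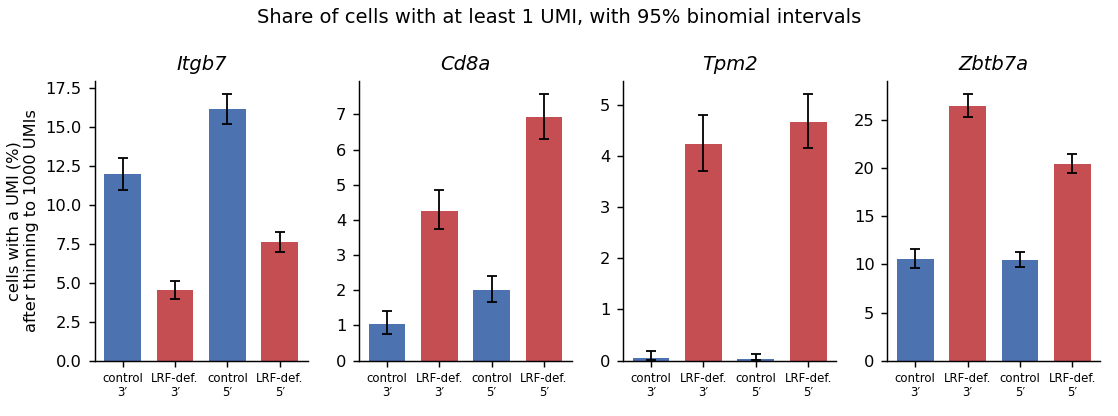
Share of cells (%) with at least 1 UMI of Itgb7, Cd8a, Tpm2 or Zbtb7a after thinning each cell to 1000 UMIs, 1 bar per library, blue for control and red for the libraries labelled LRF-deficient, with exact 95% binomial intervals. Itgb7 is at 11.97% and 16.2% in the controls and at 4.53% and 7.60% in the libraries labelled LRF-deficient, and the other 3 genes go the other way.

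Clustering of the kept cells gave 13 groups. From markers fixed in advance, cluster 3 was mature egress-stage-like (S1pr1, Il7r, Klf3) and cluster 5 interferon-signature-like (Isg15, Ifit1, Ifit3). Cluster 9 was agonist-signalled-like (Nr4a1, Egr2, Tnfrsf9, Bcl2a1b), without Pdcd1 among the markers that named it. Clusters 10 and 13 were cycling-like and cluster 12 PLZF innate-like, and 7 stayed unnamed. No cluster was named for B, myeloid, NK, erythroid or stromal cells. These clusters were made with the changed genes among others, and each had at least 1 leading gene that differed between the groups, such as S100a4 in cluster 3 and Tpm2 and Cd8a in cluster 1, so the sizes of these clusters are not compared here, although the share test set out in advance called 9 of the 13 (5 without the kit term).

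Sizes were compared in a clustering made without the 683 changed genes, chosen after the data were seen. Of its 12 clusters 2 passed the share test. Cluster 2, led by Gm4208, Cish and Kcnh3, rose from 11.3% to 31.0% of cells with the 3′ kit and from 9.07% to 19.7% with the 5′ kit (log2 fold change 1.29, SE 0.332, n = 2 per group, edgeR adjusted p = 0.0199). Cluster 4, led by Cish, Prex1 and Klf3, fell from 19.5% to 4.10% and from 13.3% to 10.6% (log2 fold change −1.27, SE 0.348, adjusted p = 0.0199). Changed genes still led these clusters, 8 of the 10 leading genes of cluster 2 (Gm4208 and Kcnh3 among them) and 2 of cluster 4 (Klf3 and Vsir), so their sizes are not shown to differ apart from the expression of those genes. The interferon-signature-like cluster 6 held 6.97% and 7.21% of control cells and 3.69% and 5.32% of the others, and did not pass (adjusted p = 0.203). The T-bet-like cluster 5 (Klrd1, Nkg7, Ccl5) held 13.1% and 14.6% against 8.92% and 11.7% (adjusted p = 0.323). The PLZF innate-like cluster 8 (Zbtb16, Il4, Plac8) held 5.26% and 5.33% against 3.84% and 3.70% (adjusted p = 0.323), and the cycling-like cluster 10 held 2.36% and 4.33% against 1.68% and 4.09% (adjusted p = 0.541). The interferon, T-bet and PLZF types are 1 cluster each here, and the same cell numbers passed when tested beside 5 groups by type in place of 12 clusters (adjusted p = 0.0293, 0.0355 and 0.0355), so these calls depend on the grouping. Changed genes were also 1 of the 10 leading genes of cluster 6, 7 of cluster 5, 5 of cluster 8 and 7 of cluster 10, and the 3 markers that named cluster 8 were all changed genes, so the sizes of these clusters carry the same limit.

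Expression was also compared within clusters, to ask whether the differences over all cells are found inside groups of like cells. In the first clustering, 10 clusters had at least 50 cells in every library and gave 1572 gene-by-cluster calls, 1502 of them in the direction of the fold change over all cells. They covered 678 genes, of which 382 had also passed over all cells. Anxa4, Rps27 and Zbtb7a passed in all 10. Among genes with a mean of at least 10 CPM in a cluster, Tpm2 was among the 3 largest rises in 9 clusters (log2 fold change 4.88 to 7.32), Crhbp in 4, and Gng3, Pnmt and Rcn3 in 3 each. Tpm2 was nearly absent from control cells, so the size of its folds is uncertain. In cluster 5 it was fitted at 7.32, beside 5.66 and 4.83 in the 3′ and 5′ pairs. Cd74, which encodes the invariant chain, Dapl1 and Myl1 were among the 3 largest falls in 3 clusters each (for Cd74 −3.22 to −1.68). Zbtb16 was among the 3 largest falls in 1 cluster, the cycling-like cluster 10 (−2.13). Its log2 fold change there was −0.51 in the 3′ pair and −2.57 in the 5′ pair. Without the kit term no cluster had a call (0, with 1254 at an unadjusted p under 0.05).

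In the same clusters Itgb7 fell in 7 of 10 (−1.80 to −0.32, median −0.853), Cd8a rose in 8 of 9 (0.891 to 2.62), Lgals1 fell in 9 of 10, Tmem158 in 7 of 10, S100a4 in 5 of 9 (median −0.808), Thy1 in 1 of 5 (median −0.1595) and Gpr15 in 2 of 7 (median −0.62). Itga4 fell in 2 of 10 (lowest −0.79), Itgae rose in 1 of 8 (highest 2.66), Ccr9 rose in 1 of 7 and Pdcd1 passed in 0 of 10. In the clusters made without the changed genes, which part the cells less by those genes, there were 2589 calls. Itgb7 fell in 10 of 10 clusters (−1.54 to −0.94), Cd8a rose in 10 of 10 (1.14 to 2.41), Tpm2 in 10 of 10 (4.87 to 8.34) and Zbtb7a in 10 of 10 (1.11 to 1.36). Over all clusters 12 control cells of the 3′ kit and 16 of the 5′ kit held a Tpm2 UMI, so the size of its folds within clusters is uncertain. Lgals1 and Tmem158 fell in 10 of 10, S100a4 in 8 of 8 (median −1.69) and Thy1 in 3 of 6 (median −1.28), and Gng3, Pnmt, Anxa4, Dbn1 and Sh3rf1 rose in 10 of 10. Ccr9 passed in 1 of 8 clusters, Itga4 in 1 of 10, where it fell by 0.63, and Itgae and Pdcd1 in 0. Gpr15, a receptor that guides T cells to the colon and was chosen after its values were seen, fell in 5 of 8 clusters (median log2 fold change −1.15 over the 8).

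**Figure D4:**
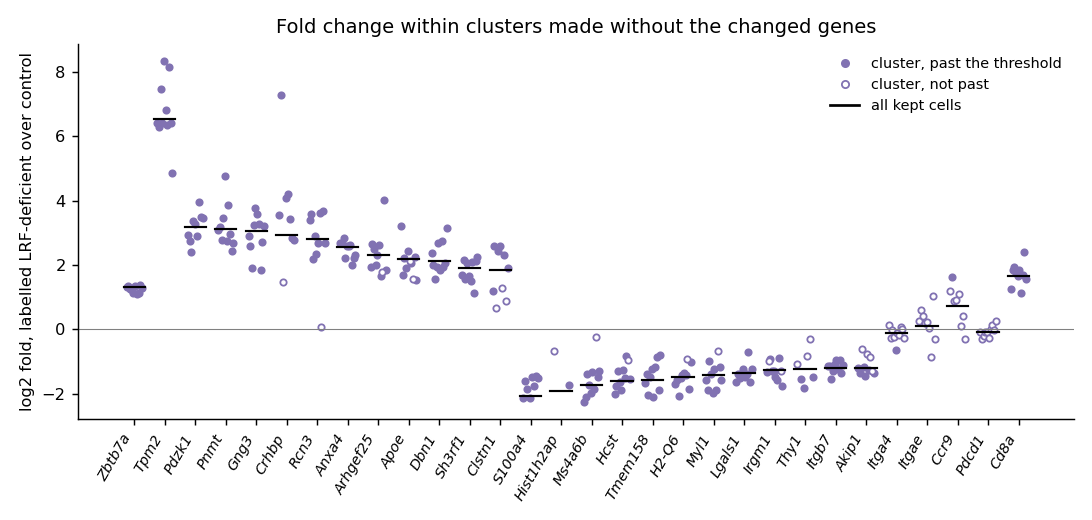
Log2 fold change, libraries labelled LRF-deficient over control, of the named genes and Cd8a within each cluster made without the changed genes; filled points passed the adjusted p of 0.05 in that cluster, open points did not, and black bars are the fold change over all kept cells. Itgb7 spans −1.54 to −0.94 and Tpm2 4.87 to 8.34 over 10 clusters.

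The 5′ kit reads the variable end of T cell receptor transcripts, so segment use was described in that pair, with 1 library per group and no test. The control had 30138 Trav and 100442 Trbv UMIs and the library labelled LRF-deficient 26764 and 96146. The share of UMIs that would have to move between segments to make the libraries equal was 6.85 points over 128 Trav segments and 3.71 points over 35 Trbv segments. With the cells of both libraries dealt at random, 200 times, it was 6.005 points on average for Trav (4.30 to 7.95) and 3.02 for Trbv (1.69 to 4.86), so by UMIs no difference in segment use was detectable. Counted by cells with a UMI of a segment it was 6.34 points for Trav, above the 3.71 to 5.946 of cells dealt at random, and 3.06 for Trbv, within 1.27 to 3.25. Dealing cells at random leaves out differences between libraries of 1 group, which this pair cannot show. Trav12-2 held 5.26% of Trav UMIs in the control and 5.52% in the other library, and was found in 7.20% (exact 95% binomial interval 6.499 to 7.955) and 7.71% (6.997 to 8.475) of the cells with a Trav UMI. Several Trav segments have near-identical copies, so their shares are uncertain.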

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

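The comparison of effects between clusters used clusters made without the changed genes, and that test and the size limits for genes listed in 1 annotation were chosen only after the results were seen.

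The effect of genotype differed between clusters for 384 of 10677 genes by a test of the difference itself (edgeR adjusted p under 0.05 over 10 clusters), of which 116 had also passed over all cells and 58 were receptor variable segments. Trbv23, a receptor segment, had the smallest p. The variable end of receptor transcripts is read by the 5′ kit, so the segment calls rest mainly on 1 library per group. They are not taken here as differences in the effect of genotype. Among other genes, Cd7, a surface receptor of T and NK cells, was higher in all 10 clusters, from 0.50 to 1.36 on the log2 scale, a range of 0.862. Cks1b, a cyclin-dependent kinase subunit, ranged over 1.17, from 0.11 in the cycling-like cluster 10 to 1.28 in the T-bet-like cluster 5. Hmgn2, a chromatin protein, ranged over 0.778, from −0.01 in cluster 10 to 0.77 in cluster 4. Ms4a4b, a membrane protein of T cells, was at −1.56 in cluster 1 and −0.02 in the PLZF innate-like cluster 8, a range of 1.54. Itgb7 (adjusted p = 0.503), Zbtb7a (0.792) and Tpm2 (0.463) did not pass this test, and Cd8a did (0.00742).

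Genes listed in only 1 of the annotations stood outside the comparison. Gm9493, counted in the 3′ pair, had 561 CPM in the library labelled LRF-deficient against 259 in the control, a ratio of 2.16 (95% counting interval 2.09 to 2.24). Rpl7a-ps5, a ribosomal pseudogene, had a ratio of 1.52 (1.42 to 1.62) in the same pair. Both have 1 library per group, with no replicate check.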

How the results depend on the processing

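The clusters made without the changed genes, the within-cluster comparison in clusters scaled per library and the fits without certain clusters were chosen only after the results were seen. No gene called both here and in an alternative changed direction, but the fit with no replicate block made 0 calls, as did each fit with 1 library left out (0 to 0). Those fits drop the kit term, the lone library is assumed to vary like the others, and in simulation they recovered none of 200 changed genes. In them the 26 named genes that had passed missed the threshold, and the fold change moved by over 1.5 times for 5 of them and for 21 of 45 other genes given with one. It turned for 3 of the latter, Ccna2, Gpr15 and Rps27. DESeq2 called 338, of which 334 were shared, and left 726 adjusted p-values unset. A filter at 10 CPM called 331 and no filter 1326; the cause was not tested. Other scalings, cell filters and cell sets gave 599 to 864. No cluster was named for another cell type, so keeping all cells gave the same sums.

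Zbtb7a without the replicate block had a log2 fold change of 1.35 and, with 1 library left out, 0.942 to 1.65, past the threshold in none of these. Ccr9 and Hist1h2ap missed the threshold in DESeq2. Irgm1 and Hist1h2ap did under the stricter filter, Irgm1 also with doublets kept and without cluster 11, and Hist1h2ap also without the cycling clusters. No gene list passed with an estimated correlation (0), a setting that also missed the raised list in simulation and so cannot check the lists. With no replicate block 12 passed, as in the fit with it.

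Cluster share tests called 9 of 13 clusters, 5 with no replicate block, 6 of 7 and 15 of 18 at the lower and higher resolution, 9 of 14 with genes scaled within each library and 2 of 12 without the changed genes. In the last clustering the interferon, T-bet and PLZF types, 1 cluster each, passed when the same cell numbers were tested beside 5 groups by type (adjusted p = 0.0293, 0.0355 and 0.0355) and not beside 12 clusters; the cluster test was kept since it had been set out in advance. Within clusters, calls numbered 0 with no replicate block, 2589 in clusters made without the changed genes and 3212 in clusters scaled per library; the cause was not tested. The correlation between kits was 0.517 at 50 CPM. The Itgb7 difference was −11.4 points at 1500 UMIs, −15.4 at 2500 and −23.2 unthinned, since more UMIs per cell raise every share. Exchanging the labels of 1 pair left 0 calls (61 of 12473 genes at an unadjusted edgeR p under 0.05). That fit puts the genotype difference into the residual spread. Few calls were thus fixed in advance, and it cannot check the calls made with the labels as given. Depth limits rare transcripts such as Cd4, at 0.875 and 1.83 CPM in the controls.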

Other observations

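The tests of shifts between the first clusters and of exchanged labels were chosen only after the results were seen, as were the genes of the first paragraph.

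Notch3 rose from 0.117 to 7.88 CPM with the 3′ kit and from 0.272 to 6.06 with the 5′ kit (log2 fold change 4.86, SE 0.342, n = 2 per group, edgeR adjusted p = 0.00194), while Dtx1, a target of Notch signalling, fell by 1.86 (SE 0.225) and Heyl, another, rose by 1.15 (SE 0.187). Gpr15 fell by 1.09 (SE 0.123, adjusted p = 0.00757), and was counted mainly with the 5′ kit, at 28.6 and 13.6 CPM against 1.23 and 0.533 with the 3′ kit. The muscle myosin light chain Myl2 rose from 0.292 to 5.98 and from 0.0452 to 2.72, and H19, an imprinted noncoding RNA, from 0.584 to 13.9 and from 2.35 to 9.67. Rps27 fell by 0.64 (SE 0.0591) with both kits, although its level differed between them, at 190 and 3089 CPM in the controls. With 1 library left out, which drops the kit term, the log2 fold change of Rps27 lay between −3.77 and 2.48, of Gpr15 between −4.80 and 2.53 and of H19 between 2.33 and 4.32.

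The differences over all cells were weighed against a shift in cell state shares. In the first clusters, made with the changed genes among others, 308 of the 350 risen genes were tested, and the fold change within clusters over that over all cells had a median of 0.871 (5th percentile 0.549, under 0.25 in 2 genes), which argues against a shift between these clusters as the whole cause of the rises. For 314 of the 333 fallen genes the median was 0.8045, but the 5th percentile was 0.111 and 24 genes were under 0.25. Among the named falls the ratio was 0.1294 for Thy1, 0.391 for S100a4, 0.635 for Ms4a6b and 0.705 for Itgb7, so a shift may account for part of the falls, which stays open. In clusters made without the changed genes the ratio was 1.041 for Thy1 and 0.817 for S100a4, with a median of 0.987 over 26 named genes. This does not decide the question, since such clusters part the cells less by those genes and may mix states that they mark. A shift between states finer than the clusters stays open, as do free RNA, an effect of the LRF deletion and Cre, which goes with the genotype.

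Among genes past the threshold with at least 10 CPM in the higher group and a 4-fold change, 16 rose, from 0.385 (Tpm2) to 30.6 CPM (Dbn1) in the controls, and 4 fell. For Tpm2, stromal cells in the libraries labelled LRF-deficient would bring collagen, but Col1a1 plus Col3a1 had 6 UMIs beside 912 of Tpm2 with the 3′ kit and 3 beside 1875 with the 5′ kit (0.00323 over both). Tpm2 rose in 9 of 9 of the first clusters. A bound set in advance, Tpm2 in at least 10% of cells at 1000 UMIs, was not met (4.23% and 4.66%). It was set too high, since Tpm2 counts spread evenly over cells would give 4.69% and 5.04%, a comparison made after the shares were seen. The shares also lay under the upper bound set in advance for stromal cells, so they do not speak against such cells. The case against stromal cells rests on the collagen counts alone. In the 5′ library labelled LRF-deficient, barcodes of at most 300 UMIs held Tpm2 at 48.5 CPM (not scaled by TMM), against 51.8 in cells. Free RNA at that level could raise Tpm2 in every cluster whatever its source, so the rise within clusters cannot decide this.

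Zbtb7a counts were higher in the libraries labelled LRF-deficient with both kits, by at least 1.07 on the log2 scale. Counts from transcript outside the deleted part could account for the lack of a fall but not, alone, for a rise. Labels exchanged in both pairs could give the rise. So could a raised level of a transcript whose counted part lies outside the deletion. These cannot be told apart here, since the floxed exons are not named in the labels and the deposited values are sums per gene. The Itgb7 share stayed lower at equal depth, by −7.44 points in the kit with the smaller difference.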
